A study of Mus musculus with 672 samples.

How the data were processed

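Single bone marrow progenitors of 4 mice aged 7 weeks, on a mixed C57BL6/129Ola background, were sorted one per well into lysis buffer and turned into sequencing libraries by the full-length single-cell protocol of Picelli and colleagues with an Illumina XT kit, per the labels' protocols. The deposited table holds whole-number read counts per gene for each cell. The authors made these counts with GSNAP 2015-09-29 and HTSeq 0.5.3p3 on build mm10, per the submitters' processing notes. The annotation release, strand setting and read layout are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The protocol uses no molecular identifiers, so a count is a read and not a molecule, and upper limits given for shares cover counting error only.

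The table lists 46078 genes, 92 spike-in RNAs and 5 HTSeq summary entries for 672 cells. Genes took 43.2% of all entries, spike-ins 6.13%, unaligned reads 33.0%, reads on no annotated feature 11.6% and ambiguous reads 6.08%. Spike-ins and summary entries stayed out of library sizes and tests. Symbols and coordinates were taken from the GENCODE annotation of GRCm38, the assembly also called mm10. Of the gene identifiers, 45143 had a symbol, and the other 935 held 0.133% of gene counts.

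Each cell was assigned to a population, a genotype and a mouse from its title. The mouse is the replicate, with 2 control mice (18218 and 18220) and 2 null mice (18217 and 18219). A cell was kept with at least 50000 nuclear gene counts, at least 1000 nuclear genes, at most 20% mitochondrial counts and at most 50% spike-in counts. These limits kept 561 cells and left out 111, of which 86 were ALPs of mice 18219 and 18220. No 2 cells had identical counts (0 pairs). No doublet caller was run, because cells were sorted one per well. The cell limits, gene lists, tests, alternatives planned and the rule for named genes were fixed before the data were examined.

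Counts of kept cells were summed into 12 libraries, 1 per mouse and population, with 53741264 to 137497554 gene counts. Genes with too few counts were removed with filterByExpr, leaving 19903. The libraries were scaled by TMM and compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 fit of 6 groups with 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Standard errors of log2 fold changes are approximate, taken as the size of the change divided by the square root of the quasi-likelihood F statistic. The common biological coefficient of variation was 86.9%. A further fit used 1 summed library per mouse (4 libraries, 21047 genes, 2 residual degrees of freedom, 68.2% variation). Levels are given as CPM computed with TMM-scaled library sizes. Where the text calls a level a mean, the SD is over 2 mice.

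The 20 gene lists were NuRD subunits, early B lineage, T lineage and Notch targets, NK and innate lymphoid, myeloid, dendritic, erythroid and megakaryocyte, stem and multipotent, S phase, G2 and M phase, p53 targets and apoptosis, interferon response, immediate early and heat shock, imprinted, germline, mature B and plasma cell, macrophage and stroma, a sex-linked check, ribosomal proteins and the mitochondrial genome. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Their p-values were adjusted over the lists of a comparison. A list called by camera is said to hold where the estimated correlation also gives an adjusted p under the threshold.

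Named genes followed a fixed rule. Mbd3 was given in every group. In each comparison up to 8 genes per direction were named, with the largest changes among those past the threshold, at a mean of at least 20 CPM, and with no overlap between mice. Predicted genes, pseudogenes, antigen receptor segments, Y-linked genes, Xist and Tsix were left out of that choice. Up to 4 members of each list with the smallest p, and 6 genes of the sorting gates, were also named. Apoe, Ly86, Ctsg, Lgals1, Dlg2, Cd63-ps and list members named beyond that number were chosen after their values were seen.

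For shares of cells with a read, each kept cell was thinned to 50000 gene counts, and the share was taken per mouse for 17 fixed genes. Shares were compared by a two-sided exact permutation test over mice. With 2 mice against 2 its smallest possible p is 0.33, so no share can pass 0.05 by that test.

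The same mouse gave all 3 populations, so the mouse number in the titles pairs the gate comparisons, and the fit with mouse as a block was an alternative. Deviations from group means of libraries of the same mouse correlated across genes by 0.0341 to 0.0694. Genes are not independent replicates in that check.

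On simulated counts for null versus control in ALP (19478 genes), the test recovered 2 of 50 genes changed 2-fold (4%), 19 of 50 changed 4-fold (38%), 33 of 50 changed 16-fold (66%) and 43 of 50 changed 64-fold (86%), with 5 false calls among 19278 unchanged genes. Each gene was drawn with the spread typical of its level, without added spread of single genes or reads from 1 large cell. Recovery in the real libraries may therefore be lower, and Mbd3 itself, 61.6-fold lower in null ALPs, was not called. In the same comparison a list of 30 genes shifted 4-fold gave a camera p of 1.98e-33 and an unshifted list 0.883 (19519 genes). Genes were drawn independently of one another, so this does not show how camera behaves when list members are correlated. A share test recovered 18 of 50 genes (36%) raised by 20 percentage points and 49 of 50 (98%) raised by 40, with 4 false calls (11749 genes). Shares were drawn with counting error and no spread between mice, so recovery in real mice may be lower.

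Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or no TMM factors within edgeR, no filter on low counts, all cells, a stricter cell filter (200000 counts, 2000 genes, 10% mitochondrial counts), thinned cells, fits of the compared libraries alone, mouse as a block, and leaving out each mouse in turn. Chosen after seeing the data were a filter asking for 10 reads in at least 10% of cells, a block for the 2 parts of the column layout (mice 18217 and 18218, and mice 18219 and 18220), a fit without the ALP libraries of mice 18219 and 18220, limma on arcsine-transformed shares of cells (mean share 5 to 99%), and alternatives for lists other than the early B and T lists.

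Explanations of a pattern were tested with bounds stated beforehand for 4 of 8 tests. Several tests changed after a result was seen. The test for reads from other wells in the early B pattern first used Ebf1 alone (gap of 30.9 percentage points) and then the 7 early B genes that rose (median gap of 10.2 percentage points), and was at last run on all 30, since those 7 had been chosen in the same mice. A test of those 7 genes for a few cells with most reads (smallest median difference 12.7 percentage points), run after an undecided test over all 30, was set aside for the same reason. The planned test for BLPs in the ALP gate, by the mixing of other genes, was undecided, and the outcome was set afterwards by Ly6d. The Ly6d test followed the sight of Ly6d shares, and Ly6d was then taken out of the early B genes used for mixing. The bound on genes near Apoe and Ablim1 was met, but the outcome was set to undecided afterwards because the base rate allows it. Intervals for Mbd3 levels are bootstraps over wells (2000 draws), where a counting interval had been foreseen, and intervals for medians are bootstraps over genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for cells, shares and plots.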

Results

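Transcripts were counted in 672 single cells sorted from the femurs and tibiae of 4 mice. Both control mice carried floxed alleles of Mbd3, and both null mice carried the deleted alleles. Mbd3 encodes a subunit of NuRD, a chromatin complex that remodels nucleosomes and removes histone acetyl groups. From each mouse 48 lymphoid-primed multipotent progenitors (LMPPs), 84 all-lymphoid progenitors (ALPs) and 36 B cell-biased lymphoid progenitors (BLPs) were sorted. LMPPs were taken as Flt3-high cells without surface IL-7 receptor, ALPs as cells with IL-7 receptor and without Ly6D, and BLPs as cells with both proteins. The design asks what loss of Mbd3 does to transcripts in each population, and how each population differs from the one before it in either genotype. After filtering, 561 cells remained, with a median of 1431484 nuclear gene counts (58286 to 12925945) and 8301 detected genes. Summed per mouse and population, libraries held 53741264 to 137497554 gene counts. Median nuclear gene counts per kept cell were lower in null libraries (1004760 to 1285444) than in control libraries (1586214.5 to 2340592). Shares of cells without thinning or with at least 10 reads are therefore not at equal depth between genotypes. In ALP, control mice kept 74 and 40 of 84 cells (mice 18218 and 18220), and null mice 79 and 42 (mice 18217 and 18219). In LMPP and BLP, 45 to 47 of 48 and 34 to 36 of 36 cells were kept per mouse. The median share of a gene's reads that came from its largest single cell was 15.0% to 34.8% per library.

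**Figure D1:**
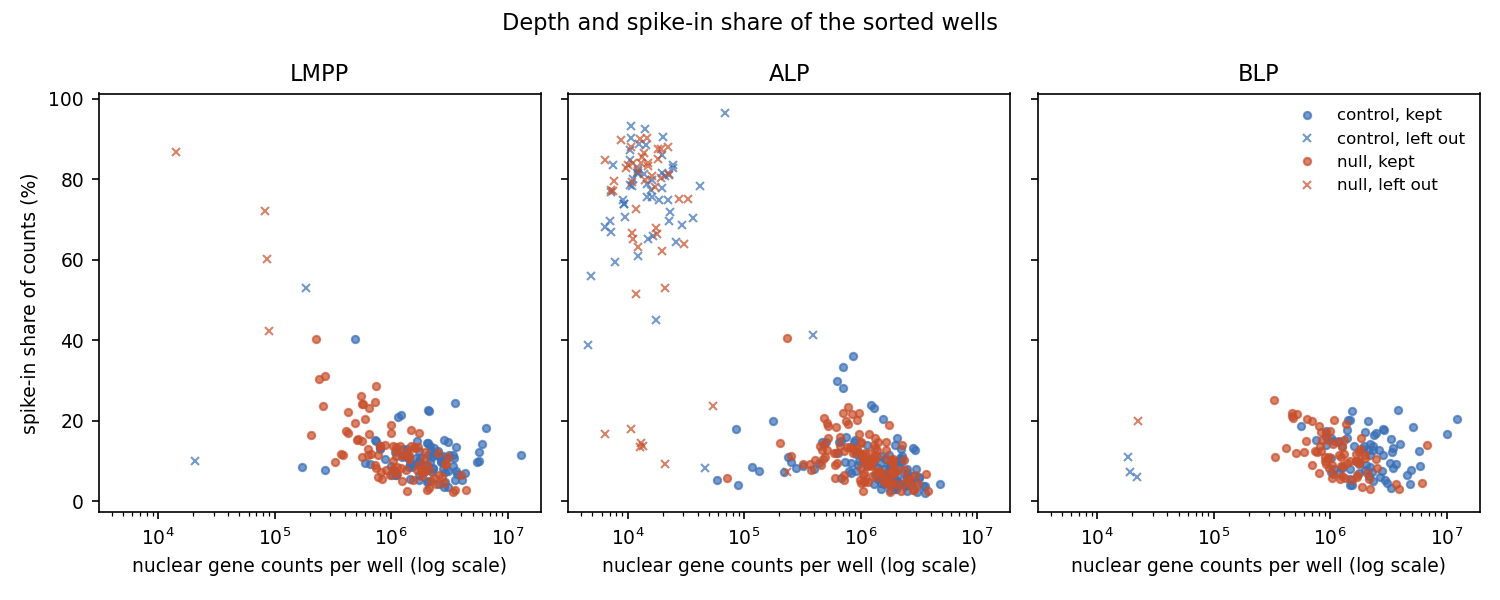
Each well is plotted by its nuclear gene counts (x, log scale) and its share of spike-in counts in percent (y), with 1 panel per population. Circles are the 561 cells kept and crosses the 111 left out, 86 of which are ALPs of mice 18219 and 18220.

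Mbd3 transcripts were low in every null library. In ALP, Mbd3 stood at 101 ± 2.39 CPM in control mice and 1.62 ± 1.79 in null mice (SD, n = 2 each). In BLP it stood at 137 ± 77.1 and 0.453 ± 0.163 CPM, and in LMPP at 92.4 ± 62.6 and 12.4 ± 17.3 CPM. The highest null library, the LMPPs of mouse 18219 at 24.7 CPM, lay below the lowest control library at 48.1 CPM, and a single cell held 1409 of its Mbd3 reads. At least 10 Mbd3 reads were found in 3 of 284 null cells and in 162 of 277 control cells (58.5%). The log2 fold changes of null over control were −2.90 ± 1.63 in LMPP, −5.95 ± 1.88 in ALP and −8.23 ± 2.11 in BLP (± approximate SE), and none passed the edgeR test (adjusted p = 0.742, 1 and 0.431). DESeq2 gave adjusted p = 0.335, 0.00171 and 5.15e-07 for the same 3 populations. Which part of Mbd3 (chromosome 10, 80392539 to 80399550, build GRCm38) was deleted is not given in the sources used here, so reads outside that part would not report the deletion.

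In null ALPs, Ebf1, a transcription factor that starts the B lineage programme, rose 8.31-fold, from 22.3 ± 3.36 to 185 ± 44.1 CPM (SD, n = 2 each). Its log2 fold change was 3.05 ± 0.26 (adjusted p = 0.0260), and it was the 1 gene of 19903 past the threshold (chromosome 11, 44617317 to 45008091), with 896 at an unadjusted p under 0.05 where chance gives 995. Of 30 early B lineage genes, 7 rose when adjusted over the list alone and none fell. Besides Ebf1 these were Pax5 (5.06 ± 0.81), which commits cells to the B lineage, Rag1 (2.57 ± 0.44), which cuts antigen receptor genes, Cd79a (4.52 ± 1.25) and Vpreb3 (3.60 ± 1.02) of the B cell receptor complexes, Pou2af1 (4.99 ± 1.44), a B cell transcriptional coactivator, and Bst1 (6.95 ± 1.73), a surface enzyme of early B cells. Pou2af1 and Bst1 were read in at most 4.76% of the null ALPs of either mouse at equal depth. Ebf1 reads were found in 68.5% ± 10.9 of null and 31.9% ± 2.68 of control ALPs at equal depth, and Cd79a reads in 47.6% ± 13.6 and 9.36% ± 9.70 (SD, n = 2 each). The early B list as a whole had a median log2 fold change of 0.38 with 18 members higher and 12 lower (camera adjusted p = 1.88e-07, and adjusted p = 0.196 with an estimated correlation). The gate gene Ly6d stood at 86.6 ± 65.9 CPM in control and 61.8 ± 36.3 in null ALPs. As a measure of BLP genes outside that list, 15 others lay 34.2% and 56.2% of the way from control ALPs to null BLPs in the ALPs of null mice 18217 and 18219, in shares of cells with a read. These 15 were chosen in part for a span of at least 20 percentage points from the same control ALPs to null BLPs. Ebf1 kept its direction without each mouse but was no longer called (adjusted p = 0.669 without 18217, 0.807 without 18218, 1 without 18219 and 1 without 18220), nor in a fit of the ALP libraries alone (adjusted p = 0.602), or with limma-voom (0.202). Nor was it called in 3 alternatives chosen after seeing the data, namely with the column layout as a block (log2 fold change 3.06, adjusted p = 0.104), without the ALP libraries of mice 18219 and 18220 (1) and with limma on shares of cells (0.0689). Over all its alternatives the adjusted p ranged from 6.10e-26 with DESeq2 to 1. The list median was 0.21 without mouse 18219 (adjusted p = 0.0923), 0.98 without mouse 18218, and 0.08 without the ALP libraries of mice 18219 and 18220 (adjusted p = 0.0113), a choice made after seeing the data.

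**Figure D2:**
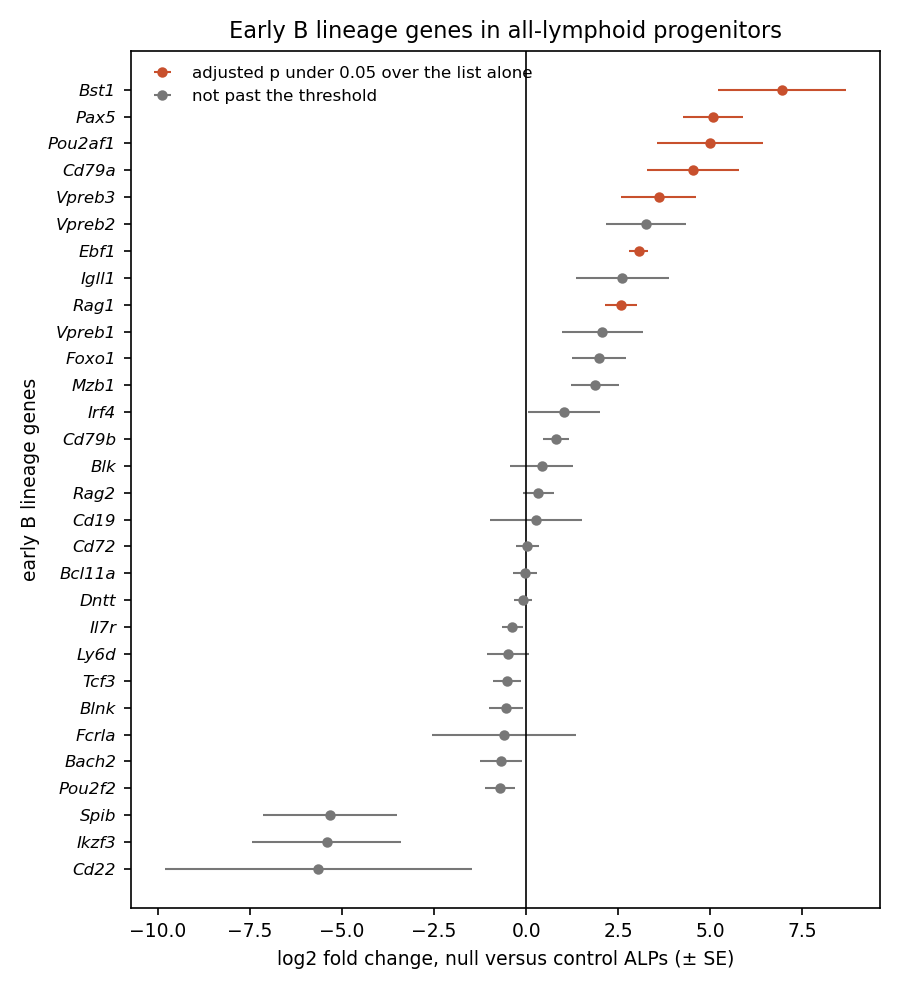
Log2 fold changes of null over control ALPs (x) are shown for 30 early B lineage genes (y), with points for the estimate and bars for its approximate standard error. The 7 genes in orange had an adjusted p under 0.05 over the list alone, and all 7 were higher in null ALPs.

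Other lists were called in null ALPs by camera alone. NK and innate lymphoid genes were lower in 12 of 15 (median log2 fold change −1.57, camera adjusted p = 0.00158, and adjusted p = 0.196 with an estimated correlation). All 24 G2 and M phase genes were lower (median −0.87, camera adjusted p = 9.52e-06, and adjusted p = 0.600 with an estimated correlation). Of that list, Mki67 was read in 38.3% ± 13.8 of null and 35.4% ± 11.1 of control ALPs at equal depth, and the mice overlapped. Stem and multipotent genes were higher in 16 of 23 (median 0.19, camera adjusted p = 0.0267, and adjusted p = 0.291 with an estimated correlation), and Fgd5, a marker of stem cells, rose when adjusted over the list alone (5.38 ± 1.20). Fgd5 stood at a low average level over all libraries (log2 CPM of 2.77), so the size of its rise is uncertain. In control mice Fgd5 was also higher in BLP than in ALP (log2 fold change 6.87 ± 1.28), so its rise does not mark a stem cell state. Genes of mature B and plasma cells, a cell type outside the gate, were lower in 6 of 8 (median −0.68, camera adjusted p = 0.0267, and adjusted p = 0.196 with an estimated correlation). Cd74, which chaperones MHC class II, rose within the dendritic list when adjusted over the list alone (2.11 ± 0.47). The 24 T lineage and Notch target genes had a median of −0.87 and were not called (camera adjusted p = 0.234). Camera calls were lost without mouse 18217 for mature B genes (median −0.79), without 18218 for G2 and M phase (−0.06) and mature B (−0.15) genes, without 18219 for NK (−2.25), stem (0.27), G2 and M phase (−0.53) and mature B (−1.12) genes, and without 18220 for NK (−0.79) and stem (0.27) genes. Without mouse 18218 the T lineage list was called (median −1.24, adjusted p = 0.00891), and without mouse 18220 its median was 0.29.

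In LMPPs no single gene passed the edgeR test for genotype (0 of 19903 genes, with 1345 at an unadjusted p under 0.05, where chance gives 995), while DESeq2 called 489 genes and limma-voom 0. G2 and M phase genes were higher in null LMPPs in 24 of 24 (median log2 fold change 1.29, camera adjusted p = 2.02e-09, and adjusted p = 0.602 with an estimated correlation), among them the spindle factor Tpx2 (2.03 ± 0.48) and the mitotic survivin gene Birc5 (2.01 ± 0.63). Mki67, a marker of cycling cells, was read in 39.1% ± 1.20 of null and 18.1% ± 1.50 of control LMPPs at equal depth (SD, n = 2 each). With at least 10 reads the shares were 29.6% ± 17.8 and 16.0% ± 4.51 and the mice overlapped. Without thinning they were 84.9% and 87.2%. Interferon response genes were lower in 21 of 21 (median −0.97, camera adjusted p = 6.33e-08, and adjusted p = 0.479 with an estimated correlation), with the antiviral genes Mx1 at −3.54 ± 0.93 and Oasl2 at −1.28 ± 0.46. Of the early B genes, 5 fell when adjusted over the list alone, namely Il7r (−2.29 ± 0.30), Irf4 (−6.96 ± 1.29), Rag1 (−1.84 ± 0.46), Bst1 (−8.39 ± 2.11) and Bach2 (−2.20 ± 0.58). Irf4 and Bst1 stood at low average levels over all libraries (log2 CPM of 2.11 and 2.29), so the size of their falls is uncertain. Il7r, the IL-7 receptor chain used for sorting, stood at 20.6 ± 8.66 CPM in control and 4.22 ± 0.716 in null LMPPs (adjusted p = 0.312). The early B list was not called (median −0.16, camera adjusted p = 0.103), but it was without mouse 18219 (−0.38, adjusted p = 0.0376) and without mouse 18220 (−0.43, adjusted p = 0.00885), and its median was 0.25 without mouse 18218. Without mouse 18217 the G2 and M phase call was lost (median 0.44, adjusted p = 0.112).

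Within other lists in LMPPs, Cd74 (2.71 ± 0.48) and Cox6a2 (1.93 ± 0.48), a marker of plasmacytoid dendritic cells, rose in the dendritic list when adjusted over the list alone, as did Fgd5 (5.60 ± 1.20) in the stem list. The size of the Fgd5 rise is uncertain, as its average level over all libraries was low (log2 CPM of 2.77). The cytokine receptor gene Il18r1 (−5.86 ± 0.92) and the plasma cell marker Sdc1 (−2.01 ± 0.34) fell when adjusted over their lists alone. Mature B and plasma cell genes were lower in 6 of 8 (median −1.51, camera adjusted p = 0.0152, and adjusted p = 0.393 with an estimated correlation). That call was lost without mouse 18217 (−2.02, adjusted p = 0.226), without 18218 (−2.10, adjusted p = 0.0598) and without 18219 (−2.01, adjusted p = 0.0916).

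In BLPs, 2 genes passed the test for genotype. Ablim1, an actin-binding protein gene, fell from 99.9 ± 46.2 CPM in control to 0.330 ± 0.0426 CPM in null mice (SD, n = 2 each), a log2 fold change of −8.24 ± 0.80 (adjusted p = 0.0405, chromosome 19, 57032733 to 57314919). Apoe, the gene of a lipid-carrying apolipoprotein, rose from 0.187 ± 0.116 to 35.8 ± 12.2 CPM, a log2 fold change of 7.59 ± 0.68 (adjusted p = 0.0405, chromosome 7, 19696109 to 19699188). Apoe fell outside the rule for named genes because its control level is low, and it was chosen after its values were seen. Apoe was also higher in null LMPPs (3.26 ± 0.55, adjusted p = 0.371) and null ALPs (3.98 ± 0.57, adjusted p = 0.314) without passing the test there. G2 and M phase genes were higher in 24 of 24 in null BLPs (median 1.72, camera adjusted p = 4.95e-12, and adjusted p = 0.877 with an estimated correlation), with the mitotic kinesin Kif23 at 1.43 ± 0.43 and the cyclin Ccnb2 at 3.06 ± 0.92. The 30 early B genes showed no call (median 0.09, camera adjusted p = 0.747), with none past the threshold over the list alone. Csf3r (3.94 ± 0.74), a receptor of the granulocyte lineage, and Cd74 (2.60 ± 0.48) rose when adjusted over the myeloid and dendritic lists alone. Without any 1 of the mice no gene was called in BLP (0 genes each without 18217, 18218, 18219 and 18220), and Ablim1 then had adjusted p = 0.646, 0.342, 0.597 and 0.814 in that order. Ablim1 also missed the threshold with limma-voom (adjusted p = 0.378), with all cells kept (adjusted p = 0.0636), with cells thinned to equal counts (−6.52, adjusted p = 0.121), in a fit of the BLP libraries alone (adjusted p = 0.543) and with the column layout as a block (adjusted p = 0.167). Its adjusted p over all alternatives ranged from 9.24e-33 with DESeq2 to 0.814. Apoe kept its direction and was no longer called without mouse 18217 (adjusted p = 0.602), 18218 (0.372), 18219 (0.597) or 18220 (0.814). It was also lost with limma-voom (0.367), in a fit of the BLP libraries alone (0.543), with the layout block (0.167), with limma on shares of cells (0.999) and with cells thinned to equal counts (4.99, adjusted p = 0.121). Its adjusted p was as low as 1.86e-37 with DESeq2. Whether the genotypes differ in strain sequence at Ablim1 or Apoe was not examined.

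With the 3 populations summed per mouse, edgeR called 0 of 21047 genes between genotypes (1482 at an unadjusted p under 0.05, where chance gives 1052), DESeq2 called 596 and limma-voom 0. Interferon response genes were lower in 18 of 21 (median −0.48, camera adjusted p = 1.77e-07, and adjusted p = 0.384 with an estimated correlation), and 6 fell when adjusted over the list alone. NK and innate lymphoid genes were lower in 12 of 15 (median −1.40, camera adjusted p = 3.57e-06, and adjusted p = 0.384 with an estimated correlation). S phase genes were higher in 21 of 22 (median 0.18, camera adjusted p = 0.00117, and adjusted p = 0.857 with an estimated correlation) and G2 and M phase genes in 24 of 24 (median 0.37, camera adjusted p = 0.00465, and adjusted p = 0.857 with an estimated correlation). Mature B and plasma cell genes were lower in 8 of 9 (median −0.87, camera adjusted p = 0.00465, and adjusted p = 0.503 with an estimated correlation). Calls were lost without mouse 18217 for S phase (0.05), G2 and M phase (0.10) and mature B (−2.97) genes, without 18218 for mature B genes (−1.03), and without 18220 for S phase (0.13) and G2 and M phase (−0.16) genes. Populations of the same mouse are not separate evidence in this sum.

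From LMPP to ALP in control mice, 35 genes rose and 19 fell. Il7r rose from 20.6 ± 8.66 to 748 ± 178 CPM (log2 fold change 5.18 ± 0.34, adjusted p = 0.000869), and so did the gate gene Ly6d (4.39 ± 0.66). Also higher were Gfra1 (8.17 ± 0.98), a receptor chain for GDNF, Cox6a2 (6.79 ± 0.59), Blnk (4.84 ± 0.55), an adaptor of B cell receptor signalling, Tnni1 (4.56 ± 0.66), Crem (4.11 ± 0.44), a cyclic AMP responsive transcription factor, and Pld4 (3.77 ± 0.49). The transcription factors Hlf (−3.65 ± 0.42) and Lmo2 (−2.64 ± 0.20) of stem and multipotent cells fell. The carbonic anhydrase gene Car2 fell from 1338 ± 248 to 110 ± 51.1 CPM (−3.60 ± 0.48). Muc13 (−7.66 ± 1.00), Ifitm1 (−4.32 ± 0.37), Wfdc17 (−3.95 ± 0.50), Akr1c13 (−2.72 ± 0.34) and Afap1l1 (−2.60 ± 0.39) fell as well. Of the other gate genes, Kit had −2.19 (adjusted p = 0.0761), Ly6a −2.41 (adjusted p = 0.283) and Flt3 −0.01. With mouse as a replicate block Gfra1, Blnk, Ly6d, Pld4, Muc13, Wfdc17, Hlf, Car2, Akr1c13 and Afap1l1 kept their direction and missed the threshold (adjusted p from 0.0524 for Pld4 to 0.118 for Ly6d).

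As groups in control mice, early B genes rose from LMPP to ALP (median log2 fold change 2.07, camera adjusted p = 2.87e-21, and adjusted p = 0.00957 with an estimated correlation). Of 30 members 6 rose, namely Ebf1 (4.69 ± 0.28), Blnk, Ly6d, Rag1 (3.60 ± 0.47), Dntt (2.05 ± 0.27) and Il7r, and 14 rose and 1 fell when adjusted over the list alone. The IL-7 receptor separates these gates in both genotypes, so the rise of Il7r was largely set by the sort. T lineage and Notch target genes were higher in 20 of 24 (median 2.60, camera adjusted p = 3.81e-09, and adjusted p = 0.0249 with an estimated correlation). Among them Hes1, a Notch target, rose (5.84 ± 0.78), with 3 members rising when adjusted over the list alone. Stem and multipotent genes were lower in 20 of 23 (median −1.29, camera adjusted p = 4.50e-17, and adjusted p = 0.00590 with an estimated correlation). Hlf, Lmo2 and the endothelial protein C receptor gene Procr (−9.12 ± 1.18) fell, and 9 fell when adjusted over the list alone. Erythroid and megakaryocyte genes were lower in 11 of 18 (median −1.28, camera adjusted p = 0.000112, and adjusted p = 0.0249 with an estimated correlation), and Car2 and Nfe2 (−2.24 ± 0.33) fell, with 5 falling when adjusted over the list alone. G2 and M phase genes were higher in 24 of 24 (median 2.28, camera adjusted p = 9.21e-17, and adjusted p = 0.172 with an estimated correlation), and 7 rose when adjusted over the list alone. With mouse as a replicate block the estimated-correlation calls changed for T lineage (median 1.95, adjusted p = 0.0842), erythroid (median −0.57, adjusted p = 0.0787) and G2 and M phase genes (median 2.20, adjusted p = 0.0163, now called), and Rag1 (adjusted p = 0.0654), Hes1 (adjusted p = 0.0737) and Procr (adjusted p = 0.0741) missed the threshold.

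The null mice showed 31 genes higher and 11 lower in ALP than in LMPP. Rag1 (8.01 ± 0.58), Ebf1 (7.51 ± 0.32), Colq (7.50 ± 0.35), Il7r (7.09 ± 0.38), Blnk (5.79 ± 0.58), Ly6d (4.62 ± 0.67), Cox6a2 (3.97 ± 0.52) and Bfsp2 (3.86 ± 0.34) rose. Wfdc17 (−3.98 ± 0.50), Car2 (−3.85 ± 0.48), Ifitm1 (−3.26 ± 0.35), Hlf (−3.06 ± 0.41), the keratin gene Krt18 (−2.75 ± 0.39), Lmo2 (−2.19 ± 0.20), Dapp1 (−1.78 ± 0.18) and the annexin gene Anxa1 (−1.71 ± 0.25) fell. Early B genes were higher in 27 of 30 (median 3.75, camera adjusted p = 1.63e-42, and adjusted p = 0.00486 with an estimated correlation), with 7 past the threshold and 20 risen when adjusted over the list alone, among them Pax5 (7.14 ± 0.90) and Dntt (1.96 ± 0.27). Stem genes were lower in 18 of 23 (median −0.95, camera adjusted p = 1.29e-10, and adjusted p = 0.0122 with an estimated correlation). Of these, Hlf, Lmo2 and Procr (−8.32 ± 1.15) fell, and 6 fell when adjusted over the list alone. Erythroid and megakaryocyte genes were lower in 14 of 18 (median −1.56, camera adjusted p = 1.16e-06, and adjusted p = 0.0122 with an estimated correlation), and 5 fell when adjusted over the list alone. That camera call was lost without mouse 18219 (median −1.43, adjusted p = 0.0741). In the fit with mouse as a replicate block Blnk, Ly6d, Cox6a2, Wfdc17, Car2, Hlf, Krt18, Anxa1, Procr and Pax5 missed the threshold (adjusted p from 0.0569 for Blnk to 0.118 for Anxa1), and Nfe2 fell (−2.07, adjusted p = 0.0328). T lineage genes were higher in 19 of 24 (median 1.66, camera adjusted p = 0.000162, and adjusted p = 0.104 with an estimated correlation).

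The counts of single genes between LMPP and ALP fell when any 1 mouse was left out. Mice of the other genotype enter such a comparison only through the shared spread, filter and scaling of the fit. A fall without a mouse of the other genotype therefore does not show that the comparison rests on that mouse. In control mice the 54 genes became 7 without mouse 18217, 1 without 18218, 7 without 18219 and 0 without 18220, and in null mice the 42 genes became 0, 7, 0 and 7 in that order. A fit with mouse as a replicate block called 32 and 22 genes. Without the ALP libraries of mice 18219 and 18220, chosen after seeing the data, 5 and 7 were called.

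Further lists were called by camera between LMPP and ALP and lost with an estimated correlation. In control mice, myeloid genes were lower in 16 of 19 (median −1.02, camera adjusted p = 0.00928, and adjusted p = 0.253 with an estimated correlation), with 3 risen and 3 fallen when adjusted over the list alone. Interferon genes were lower in 19 of 21 (median −0.78, camera adjusted p = 6.18e-05, and adjusted p = 0.253 with an estimated correlation). S phase genes were higher in 21 of 22 (median 0.61, camera adjusted p = 4.38e-06, and adjusted p = 0.332 with an estimated correlation), and ribosomal protein genes lower in 71 of 83 (median −0.22, camera adjusted p = 9.32e-05, and adjusted p = 0.332 with an estimated correlation). NK genes had a median of 1.95 (camera adjusted p = 0.0477, and adjusted p = 0.253 with an estimated correlation) and dendritic genes of 0.17 (camera adjusted p = 0.00991, and adjusted p = 0.253 with an estimated correlation). With mouse as a replicate block the NK call was lost (adjusted p = 0.0629), and immediate early and heat shock genes were called (median −0.75, camera adjusted p = 0.00331, and adjusted p = 0.0868 with an estimated correlation). Without mouse 18218 the S phase (median 0.34) and interferon (median −0.01) calls were lost. The NK call was lost without each mouse, with medians from 0.73 without 18220 to 2.50 without 18218, and 1.94 without 18217 and 18219. The dendritic call was also lost without each mouse, with medians of 0.31, 0.54, 0.30 and −0.09 without 18217, 18218, 18219 and 18220.

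In null mice, S phase genes were higher in ALP than in LMPP in 22 of 22 (median 0.49, camera adjusted p = 2.95e-05, and adjusted p = 0.404 with an estimated correlation). Macrophage and stroma genes had a median of −3.37 over 9 genes (camera adjusted p = 0.0131, and adjusted p = 0.104 with an estimated correlation). Dendritic genes had a median of 0.27 (camera adjusted p = 0.0131, and adjusted p = 0.286 with an estimated correlation), mitochondrial genes of 0.30 (camera adjusted p = 0.0391, and adjusted p = 0.404 with an estimated correlation) and ribosomal protein genes of −0.14 (camera adjusted p = 0.0485, and adjusted p = 0.655 with an estimated correlation). The sex-linked list was called with mouse as a replicate block (median 0.66, camera adjusted p = 0.0451, and adjusted p = 0.311 with an estimated correlation). G2 and M phase genes were not called (median −0.27, camera adjusted p = 0.595). Calls were lost without mouse 18217 for macrophage (−0.77), dendritic (0.27) and ribosomal (−0.10) genes. Without 18219 they were lost for S phase (0.01), macrophage (−2.45), dendritic (0.12), mitochondrial (0.38) and ribosomal (−0.10) genes, and without 18220 for dendritic genes (0.15).

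From ALP to BLP in control mice, Ebf1 rose from 22.3 ± 3.36 to 247 ± 27.9 CPM (log2 fold change 3.47 ± 0.26, adjusted p = 0.0107) and was the 1 gene past the threshold. It was also called with mouse as a replicate block (adjusted p = 0.0275). Ly6d, the protein that separates the gates, went from 86.6 ± 65.9 to 3271 ± 675 CPM (5.24 ± 0.69) without passing the test (adjusted p = 0.146). Early B genes were higher in 27 of 30 (median 1.91, camera adjusted p = 3.04e-25, and adjusted p = 0.0159 with an estimated correlation). When adjusted over the list alone 14 rose, among them Pax5 (5.50 ± 0.83), Cd79a (5.60 ± 1.32) and the surrogate light chain genes Igll1 (8.04 ± 1.56) and Vpreb1 (6.12 ± 1.31), and 2 fell, Dntt (−0.79) and Ikzf3 (−6.07). In the fit with the replicate block for mouse the list had a median of 1.85 (adjusted p = 0.0563 with an estimated correlation). Interferon genes were lower in 18 of 21 (median −1.26, camera adjusted p = 4.25e-07, and adjusted p = 0.461 with an estimated correlation), and Oas1a, Oasl2 and Rsad2 fell when adjusted over the list alone. G2 and M phase genes were lower in 24 of 24 (median −1.31, camera adjusted p = 4.25e-07, and adjusted p = 0.461 with an estimated correlation), and NK genes in 12 of 15 (median −1.04, camera adjusted p = 0.0383, and adjusted p = 0.461 with an estimated correlation). With the replicate block NK genes were not called (adjusted p = 0.0775). Mice 18217 and 18219 are null mice and enter this control comparison only through the shared spread, filter and scaling. Ebf1 was not called without mouse 18217 (adjusted p = 0.211), 18218 (0.509), 18219 (0.226) or 18220 (1). The NK call was lost without 18217 (median −1.04), 18219 (−1.04) and 18220 (−0.12), and the interferon call without 18220 (−0.28, adjusted p = 0.243).

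In null mice, edgeR called 0 genes between ALP and BLP (1274 at an unadjusted p under 0.05, against 995 by chance), while DESeq2 called 448 and limma-voom 0. Ly6d had a log2 fold change of 5.06 ± 0.68 (adjusted p = 0.266). Early B genes were higher in 28 of 30 (median 1.10, camera adjusted p = 6.19e-15, and adjusted p = 0.0399 with an estimated correlation), and Vpreb1 (5.05 ± 1.24), Igll1 (7.00 ± 1.48), Ly6d and the transcription factor gene Spib (8.92 ± 2.12) rose when adjusted over the list alone. Ly6D protein separates these gates, so the rise of Ly6d was largely set by the sort. The list had a median of 1.14 with mouse as a replicate block (adjusted p = 0.0649 with an estimated correlation), and mitochondrial genes were called (median 0.20, camera adjusted p = 0.0396, and adjusted p = 0.518 with an estimated correlation). Stem genes were lower in 17 of 23 (median −0.28, camera adjusted p = 9.41e-05, and adjusted p = 0.110 with an estimated correlation), with Mecom, Hlf, Cd34 and Mn1 falling when adjusted over the list alone. That camera call was lost without mouse 18219 (median −0.24, adjusted p = 0.0664). All 24 G2 and M phase genes were higher (median 1.22, camera adjusted p = 4.16e-10, and adjusted p = 0.423 with an estimated correlation).

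The difference between genotypes in the step from LMPP to ALP was tested as an interaction. Early B genes gained more in null than in control mice in 20 of 30 (median difference 0.85, camera adjusted p = 9.13e-09, and adjusted p = 0.233 with an estimated correlation), and 7 rose when adjusted over the list alone. All 24 G2 and M phase genes gained less (median −2.46, camera adjusted p = 3.00e-15, and adjusted p = 0.438 with an estimated correlation). T lineage genes had a median of −1.14 (camera adjusted p = 0.0376, and adjusted p = 0.562 with an estimated correlation) and interferon genes of 0.92 (camera adjusted p = 0.00814, and adjusted p = 0.593 with an estimated correlation). In edgeR 0 single genes were called (1044 at an unadjusted p under 0.05, against 995 by chance), DESeq2 called 239 and limma-voom 0. With mouse as a replicate block the G2 and M phase list was called with an estimated correlation (median −2.12, adjusted p = 0.0311), and the T lineage camera call was lost (adjusted p = 0.147). The T lineage call was also lost without mouse 18217 (median −0.88), 18219 (−0.88) and 18220 (−0.44), and the interferon call without 18217 (0.50) and 18218 (0.01).

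For the step from ALP to BLP, early B genes gained less in null mice in 17 of 30 (median difference −0.33, camera adjusted p = 0.00307, and adjusted p = 0.415 with an estimated correlation). All 24 G2 and M phase genes gained more (median 2.49, camera adjusted p = 9.77e-18, and adjusted p = 0.415 with an estimated correlation). T lineage genes had a median of 1.36 (camera adjusted p = 0.0176, and adjusted p = 0.415 with an estimated correlation), stem genes of −0.39 (camera adjusted p = 0.0176, and adjusted p = 0.415 with an estimated correlation) and interferon genes of 0.47 (camera adjusted p = 0.0143, and adjusted p = 0.770 with an estimated correlation). Single genes numbered 0 in edgeR (1269 at an unadjusted p under 0.05, against 995 by chance), 351 in DESeq2 and 1 in limma-voom. With mouse as a replicate block, G2 and M phase genes were called with an estimated correlation (median 2.47, adjusted p = 0.0206), T lineage genes were not called (adjusted p = 0.0526), and immediate early and heat shock genes were (median −0.47, camera adjusted p = 0.0400, and adjusted p = 0.379 with an estimated correlation). Without mouse 18217 the T lineage call was lost (2.18). Without 18219 the early B (−0.06), T lineage (1.45), stem (−0.44) and interferon (0.24) calls were lost, and without 18220 the early B (−0.23), T lineage (0.37), stem (−0.38) and interferon (0.27) calls.

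A signature of control cells was taken as the 117 genes higher and the 71 genes lower in control BLPs than in control LMPPs. In null against control ALPs, 66 of the 117 genes were higher (56.4%, median log2 fold change 0.10, camera adjusted p = 0.00854, and adjusted p = 0.131 with an estimated correlation). Of the 71 genes lower in BLP, 47 were also higher (66.2%, median 0.28, camera adjusted p = 4.30e-05, and adjusted p = 0.0270 with an estimated correlation), so both parts lay in the same direction. The same control mice define the signature and serve as controls in the comparison. Without mouse 18217 the medians were −0.06 and −0.07, without 18219 they were −0.32 and −0.08, and without 18218 the first was 0.50 over 3 genes (adjusted p = 0.0979), none of them called.

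Shares of cells with a read were compared for 17 fixed genes at 50000 counts per cell. In ALP, Rag1 was read in 71.2% ± 3.09 of null and 34.1% ± 12.9 of control cells, Pax5 in 18.3% ± 4.41 and 1.93% ± 0.812, Igll1 in 18.3% ± 4.41 and 2.60% ± 0.143, and Ly6d in 32.6% ± 2.28 and 41.1% ± 16.1 (SD, n = 2 each). In BLP, Ebf1 was read in 70.4% ± 1.40 of null and 79.8% ± 7.78 of control cells. In LMPP, Ebf1 was read in 7.59% ± 1.30 of null and 3.19% ± 4.51 of control cells, Rag1 in 3.24% ± 1.44 and 8.51% ± 0, and Il7r in 17.4% ± 2.54 and 25.5% ± 6.02. Mbd3 was read in 3.16% ± 4.48 of null and 54.8% ± 10.4 of control ALPs. Mice of the 2 genotypes did not overlap in 20 of 51 comparisons of a gene in a population, where chance gives 17, and the exact permutation p of such a comparison is 0.33, the smallest possible with 2 mice each. With at least 10 reads Igll1 was found in 6.66% ± 4.05 of null and 2.60% ± 0.143 of control ALPs. By the same rule in null and control LMPPs, Il7r was found in 2.17% and 24.5%, Rag1 in 0% and 5.32%, and Ebf1 in 0% and 1.06%. Without thinning, the mean shares of null and control ALPs were 93.8% and 75.2% for Ebf1, 87.2% and 65.7% for Rag1, 38.1% and 31.6% for Pax5, 73.8% and 24.3% for Igll1, 36.3% and 78.7% for Mbd3, and 82.7% and 78.4% for Ly6d. They were 64.3% and 75.5% for Ebf1 in LMPP, 100% and 100% for Ebf1 in BLP, 61.9% and 73.4% for Rag1 in LMPP, and 91.4% and 97.9% for Il7r in LMPP.

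**Figure D3:**
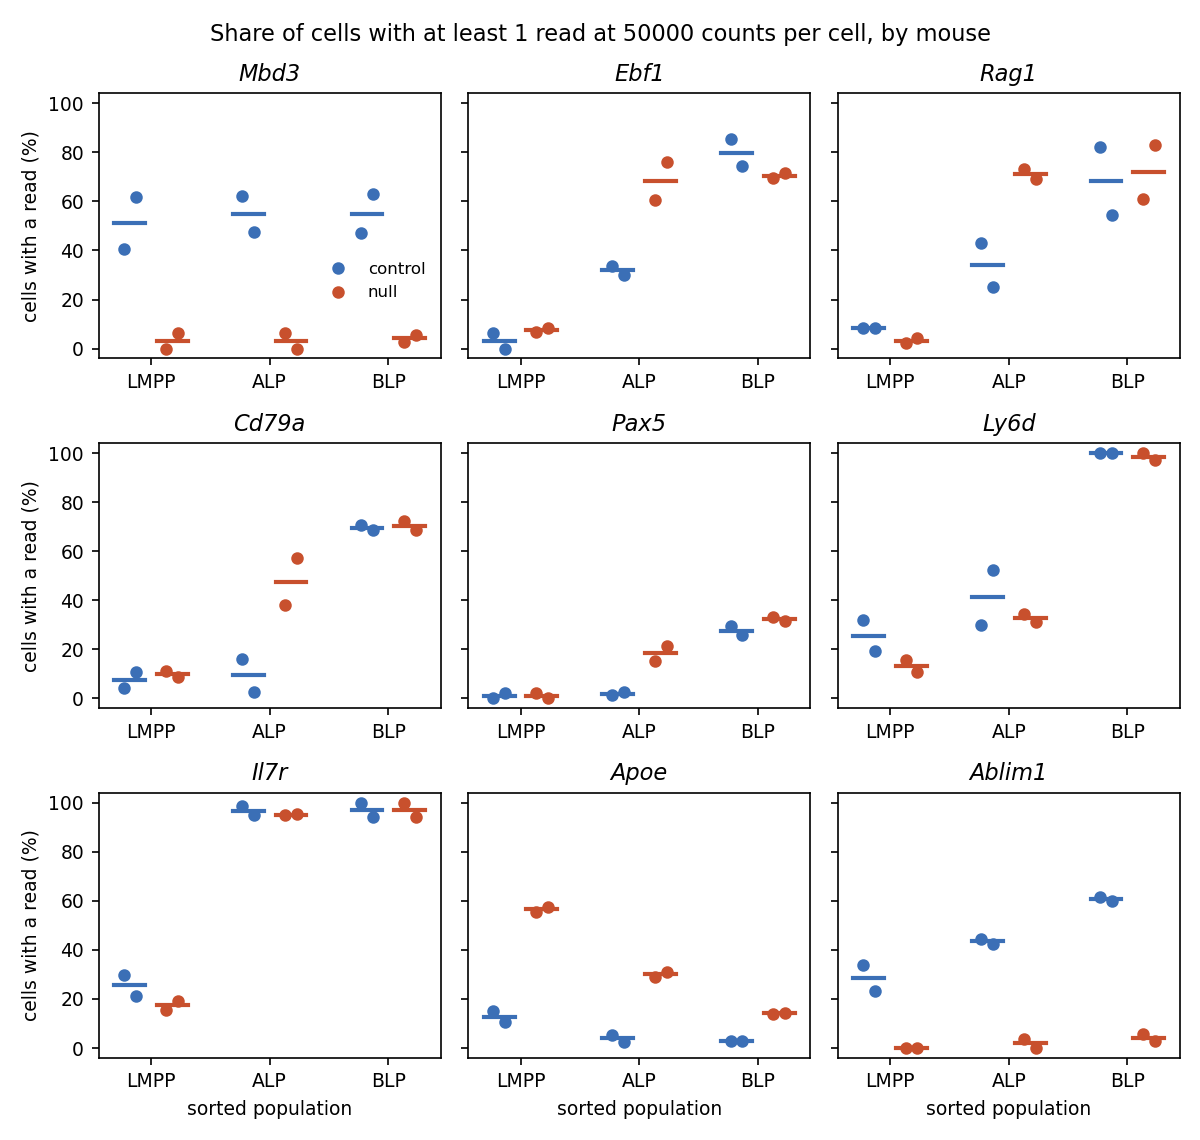
The share of cells with at least 1 read at 50000 counts per cell (y, percent) is shown for 9 genes in LMPP, ALP and BLP (x), with points for single mice and lines for the mean of control (blue) and null (orange) mice. In ALP, Ebf1 averages 68.5% in null and 31.9% in control mice, and Mbd3 3.16% and 54.8%.

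Further lists were not called between genotypes in any population. In LMPP, ALP and BLP in that order, the median log2 fold changes were 0.15, 0.10 and 0.08 for NuRD subunits, −0.60, −0.07 and −0.16 for myeloid genes, 0.05, −0.29 and −0.18 for dendritic genes, 0.46, −0.04 and −0.11 for erythroid and megakaryocyte genes, and −0.14, 0.46 and 0.13 for p53 targets and apoptosis genes. Immediate early and heat shock genes had 0.03, 0.28 and −0.15, imprinted genes −0.02, −0.05 and −0.55, the 4 germline genes −1.17, 0.65 and −4.20, macrophage and stroma genes 1.18, −0.73 and 0.00, and the sex-linked check −0.26, 0.12 and 0.21. Ribosomal protein genes had −0.06, 0.04 and −0.10, and mitochondrial genes −0.09, 0.02 and 0.18. Lists called in another comparison were not called in LMPP for T lineage (0.63), NK (−0.05), stem (−0.07) and S phase genes (0.39), in ALP for S phase (0.22) and interferon genes (−0.31), or in BLP for T lineage (0.68), NK (−0.92), stem (−0.40), S phase (0.09), interferon (0.09) and mature B genes (−0.54). Median, mean and test differed in sign for NuRD subunits in all 3 populations, for stem, immediate early and sex-linked genes in LMPP, for myeloid, dendritic, erythroid and ribosomal genes in ALP and BLP, and for imprinted and macrophage genes in BLP. In the gate comparisons they differed for p53 and macrophage genes from LMPP to ALP in control mice, for germline genes in null mice, for myeloid, germline, mature B and sex-linked genes from ALP to BLP in control mice, and for erythroid, p53, immediate early, mature B and ribosomal genes in null mice. They differed in the interactions for dendritic and imprinted genes in both steps and for myeloid, mature B, macrophage and ribosomal genes from ALP to BLP, and in the summed libraries for dendritic, stem, p53 and ribosomal genes.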

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

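Of the tests reported here, those of BLPs by their Ly6d reads, of a few cells with most reads and of reads from other wells in the early B pattern were chosen after the result was seen, and Apoe and Ablim1 were singled out after their values were seen.

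The genotypes differed in 4 gene lists in the step from LMPP to ALP by camera on the interaction, and without a block for mouse none of these held with an estimated correlation. The median log2 differences were 0.85 for early B genes (adjusted p = 0.233 with an estimated correlation), −1.14 for T lineage genes (adjusted p = 0.562), −2.46 for G2 and M phase genes (adjusted p = 0.438) and 0.92 for interferon genes (adjusted p = 0.593). In the step from ALP to BLP they differed in 5 lists. The medians were −0.33 for early B genes (adjusted p = 0.415 with an estimated correlation), 1.36 for T lineage genes (adjusted p = 0.415), −0.39 for stem genes (adjusted p = 0.415), 2.49 for G2 and M phase genes (adjusted p = 0.415) and 0.47 for interferon genes (adjusted p = 0.770). With mouse as a replicate block the G2 and M phase list was called with an estimated correlation in both steps (median −2.12, adjusted p = 0.0311, and median 2.47, adjusted p = 0.0206), while the T lineage camera calls were lost (adjusted p = 0.147 and 0.0526). Both steps share the ALP libraries, so opposite signs in the steps are not separate evidence.

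The share of cells with an Ebf1 read at equal depth differed between genotypes in opposite directions. It was higher in both null mice by 36.6 percentage points in ALP and by 4.40 in LMPP, and the BLP difference was −9.35 percentage points, with no overlap between mice. The LMPP difference rests on few cells with a read (7.59% ± 1.30 of null and 3.19% ± 4.51 of control cells) and is smaller than the control SD. In LMPP this depended on how a cell with a read was counted. Without thinning the difference was −11.3 percentage points in LMPP (64.3% of null and 75.5% of control cells) and 18.6 in ALP. In BLP it was 0, but Ebf1 was then read in 100% of cells of both genotypes, so no difference could appear. With at least 10 reads it was −1.06 in LMPP, −10.6 in BLP and 39.8 in ALP. Null cells held fewer counts, so neither of these alternatives is at equal depth. For Rag1 the difference was 37.1 percentage points in ALP and −5.27 in LMPP. These differences between populations were not tested.

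Of 30 early B genes 18 were higher and 12 lower in null ALPs (median log2 fold change 0.38, adjusted p = 0.196 with an estimated correlation), and 7 rose when adjusted over the list alone. As a set, 15 other genes frequent in null BLPs and rare in control LMPPs were found in more null ALPs. They also had to span at least 20 percentage points from control ALPs to null BLPs. That choice used the same control ALPs as the base, which can raise the estimate. A genotype difference shared by ALPs and BLPs would also count as mixing. Read as mixing, the other genes would make 34.2% and 56.2% of the null ALPs of mice 18217 and 18219 BLPs (95% bootstrap intervals 25.9 to 48.7 and 34.4 to 79.4). The 7 early B genes used for mixing gave 46.9% and 78.3%. They were Ebf1, Foxo1, Cd79a, Vpreb2, Rag1, Mzb1 and Blk, a set that differs from the 7 that rose. Ly6d was read in 98.6% of null BLPs, so BLPs as the whole source would need Ly6d reads in 68.1% and 86.1% of null ALPs, or in at least 51.7% and 70.9% with the low end of the early B estimate and the lowest control mouse as base. They were found in at most 34.2%, with upper limits of 45.7% and 47.1% (with Ly6d kept among the early B genes, 65.0% and 84.1% would be needed). This argues against BLPs with Ly6d reads as frequent as in sorted null BLPs as the whole source of the early B difference. Sorting on Ly6D is meant to remove such cells, so BLPs that passed the sort could hold fewer Ly6d reads. A smaller share of BLPs, and cells with BLP genes but few Ly6d reads, stay open. A few cells with most reads stay open over the 30 genes (smallest median difference in share 1.20 percentage points, with lower bounds down to −1.39), and Pou2af1 and Bst1 were read in at most 4.76% of the null ALPs of either mouse. Reads from other wells stay open over the list as well, since in shares of ALPs with 10 or more reads the lowest null mouse differed from the highest control mouse by a median of −0.162 percentage points (−2.60 to 1.18), with 12 of 30 genes above 0. Among early B genes fixed beforehand for shares, at least 10 Ebf1 reads were found in 68.6% of null and 28.7% of control ALPs. The shares were 72.5% and 35.3% for Rag1, 46.9% and 7.43% for Cd79a, and 17.0% and 1.25% for Pax5. Vpreb1 (6.03% and 1.25%) and Igll1 (6.66% and 2.60%) differed less. Il7r (95.7% and 98.1%), Ly6d (40.6% and 39.6%) and Dntt (100% in both) hardly differed. For Ebf1, Rag1 and Cd79a these shares argue against a few cells, or cells with only a few reads, as the source. These genes are also among the 7 that rose, so they do not speak for the list. An effect of Mbd3 loss on early B genes within ALPs remains a hypothesis. A smaller share of BLPs, the 2 mice per genotype and the estimated correlation leave it open. Over the list, a few cells and reads from other wells leave it open too.

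The 111 wells left out held a median of 14650 nuclear gene counts, a signal outside the main measurement, with 77.1% spike-in counts against 9.92% in kept cells and 63.9% mitochondrial counts against 6.17%. In left-out wells of null mice Mbd3 stood at 35.9 reads per 1e+06 nuclear counts (19.6 to 60.3, 45 reads in 52 wells), near the 34.8 in left-out wells of control mice. That is 17.0 times the level in kept null ALPs (2.11, 0.348 to 5.06), which argues against damaged null cells as the only source. Reads from other wells are a candidate source, since all kept cells together stood at 74.8 (60.2 to 89.5). No biological explanation was tested.

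Apoe was read in more null than control cells by 43.7, 26.1 and 11.2 percentage points in LMPP, ALP and BLP, and Ablim1 was read in fewer null cells in each population. Over 8 macrophage genes the median difference was 0, −0.676 and 0 percentage points, at most 0% of the Apoe difference (upper ends of the intervals 2.54%, 0% and 11.0%), which argues against macrophage RNA, from a cell type that the lineage markers of the sort are meant to remove. C1qa was read in 1.11% of null LMPPs and in 0% of null ALPs and BLPs, where Apoe was read in 56.5%, 30.0% and 14.1%. Cd74 went the other way and was read in more null than control cells in each population (30.7% and 17.0% in LMPP, 25.3% and 21.2% in ALP, 28.2% and 10.1% in BLP), and 2, 2 and 5 of the 8 genes were read in no cell of either genotype. Cells that express Apoe without these genes, such as other stroma, were not tested. A segment of another strain around either gene may still be present. Of 35 neighbouring genes within 1 Mb, 0 differed in 2 or more populations (upper limit 10.0%), where the rate over all genes (1.50%) gives 0.524. Loss of Mbd3, a variant in either gene and the mixed strain background of the null mice stay open too.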

How the results depend on the processing

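Chosen after seeing the data were the block for the column layout, the fit without the ALP libraries of mice 18219 and 18220, the filter on 10 reads in at least 10% of cells, limma on shares of cells, and all alternatives for lists other than the early B and T lists. Signs of the 35 results for genes named by size were kept in 592 of 592 fits that gave a fold change, and they passed the threshold in 385 of 627. Another 15 gene results, among them Apoe, were named after their values were seen, and kept their sign in 240 of 240 fits that gave a fold change and their side of the threshold in 197 of 250, with 31 no longer called and 22 newly called. Counts of genes stayed within 1.5 times in 92 of 172 fits. List results were recomputed for the early B and T lists between genotypes, the signature and lists that camera called as reported, so lists called under an alternative alone and estimated correlations with a block are not counted here. Of these, 720 of 924 kept direction and side of the threshold, 186 were no longer called, 3 became called, 7 moved and 8 reversed. Of 216 shares, 108 stayed within 1 SD between mice and 108 moved, and all of these alternatives used other depths or read minimums. DESeq2 size factors and no TMM factors moved no count by over 1.5 times. The cause was not tested for any difference below unless one is stated. Leaving out a mouse leaves 1 mouse in a genotype, which is assumed to vary like the other groups, and removes residual degrees of freedom, as does a block or a fit of few libraries. In a gate comparison within 1 genotype, mice of the other genotype enter only through the shared spread, filter and scaling. With at least 1 read, what depth limits was not separated from reads of other wells. Ebf1 was read in 31.9% of control ALPs at equal depth, in 75.2% without thinning, and in 67.6% of left-out wells. At least 10 Ebf1 reads were found in 28.7% of control ALPs and in 0% of left-out wells. Those wells held a median of 14650 nuclear gene counts, so these shares are not at equal depth. A median of 15.0% to 34.8% of a gene's reads came from 1 cell.

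Counts are given for null versus control in LMPP, ALP and BLP, for ALP versus LMPP in control and null mice, and for BLP versus ALP in control and null mice, where the values reported were 0, 1, 2, 54, 42, 1 and 0. Without the filter on low counts they were 8, 6, 11, 179, 165, 34 and 10, with 3 and 1 for the interactions and 1 for summed libraries. DESeq2 gave 489, 276, 800, 920, 926, 595 and 448, with 239 and 351 for the interactions and 596 for summed libraries. Thinned cells gave 0, 3, 0, 166, 229, 14 and 7, with 2 for summed libraries. With limma-voom they were 0, 0, 0, 96, 27, 2 and 0, with 1 for the interaction from ALP to BLP. Fits of the libraries compared gave 0, 0, 0, 0, 1, 0 and 0, and all cells gave 1 in BLP. The filter on 10 reads gave 5, 3, 7, 120, 121, 17 and 0, with 5 for summed libraries. Limma on shares gave 4, 7, 2, 319, 391, 12 and 1. With the layout block ALP and BLP had 0 and 0 genes. Without the ALP libraries of mice 18219 and 18220, 0 genes were left in ALP, 5 and 7 for ALP versus LMPP, and 0 for BLP versus ALP in control mice.

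Mouse as a replicate block gave 32 and 22 genes for ALP versus LMPP in control and null mice. Besides the calls of genes and lists given with the results it changed no other call. No block for mouse could be fitted to null versus control, since each mouse has 1 genotype.

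Leaving out 1 mouse gave 0 to 7 genes for ALP versus LMPP in control mice, 0 to 7 in null mice, and 0 to 0 for BLP versus ALP in control mice and for null versus control in ALP and BLP. The early B median ranged from −0.43 to 0.25 in LMPP and from 0.21 to 0.98 in ALP, and the T lineage median from −0.0611 to 1.43 in LMPP and from −1.24 to 0.29 in ALP. The early B list in LMPP became called without mouse 18219 (−0.38) and 18220 (−0.43), and the list in ALP was lost without 18219 (0.21). The signature medians ranged from −0.32 to 0.50 for genes higher in BLP and from −0.0750 to −0.0659 for genes lower in BLP, the latter without 18219 and 18217 alone. Without mouse 18218 no genes lower in BLP, and without 18220 no signature, could be formed, and without 18218 the genes higher in BLP numbered 3. Dendritic genes from LMPP to ALP in control mice ranged from −0.0858 without 18220 to 0.54 without 18218, and G2 and M phase genes in summed libraries from −0.16 without 18220 to 1.43 without 18218.

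With an estimated correlation and with fry, the early B median in ALP is unaltered at 0.38 by construction, with adjusted p = 0.196 and 0.165. The signature genes higher in BLP likewise keep 0.10, with adjusted p = 0.131. In LMPP the early B median was 0.0819 with thinned cells and 0.0272 with the filter on 10 reads. In ALP the T lineage median was 0.0660 without the ALP libraries of mice 18219 and 18220 and 0.24 with the filter on 10 reads, and without those libraries the signature genes lower in BLP had 0.0934 (adjusted p = 0.0537). Dendritic genes from LMPP to ALP in null mice had −0.0440 with thinned cells and −0.0383 without those libraries.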

Other observations

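All share tests named here were chosen after the result was seen, as were the genes, and they used limma on arcsine-transformed shares of cells at equal depth (11761 genes).

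Besides Mbd3, null cells differed from control cells in the share of cells with a read for few genes. Ly86, which pairs with a toll-like receptor homologue of B cells, was read in 25.1% ± 1.51 of null and 73.2% ± 6.07 of control ALPs (SD, n = 2 each, adjusted p = 0.000117). It was read in 61.9% ± 10.7 of null and 81.1% ± 2.44 of control BLPs, and in 4.30% ± 2.94 and 12.8% ± 0 of LMPPs. Ablim1 fell in all 3 populations, from 28.7% ± 7.52 to 0% ± 0 of LMPPs (adjusted p = 6.96e-05), from 43.5% ± 1.48 to 1.90% ± 2.69 of ALPs (adjusted p = 8.31e-07) and from 60.9% ± 1.25 to 4.21% ± 1.91 of BLPs (adjusted p = 3.14e-05). Apoe rose from 12.8% ± 3.01 to 56.5% ± 1.34 of LMPPs (adjusted p = 0.000458) and from 3.95% ± 2.05 to 30.0% ± 1.30 of ALPs (adjusted p = 0.00668). Cd79a (adjusted p = 0.00769), Dlg2 (adjusted p = 0.00384) and Cd63-ps (adjusted p = 0.0313) rose in ALPs. Cd63-ps is a pseudogene whose reads are uncertain because they can come from Cd63. Lgals1, a galectin gene, fell in LMPPs (adjusted p = 0.00282). Mbd3 passed in LMPP, ALP and BLP (adjusted p = 4.41e-05, 7.51e-07 and 0.00179). Of the genes in this paragraph, edgeR called only Ablim1 and Apoe between genotypes, both in BLP alone. By edgeR, Ly86 had log2 fold changes of −2.80 ± 0.76 in ALP and −2.24 ± 0.76 in LMPP and missed the threshold. The share fit has 2 mice per group, pools its estimate of spread over all genes, and was not repeated with a mouse left out.

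Ctsg, a protease of granulocyte precursors, was read in more null than control cells in each population. The shares were 26.1% ± 0.802 and 8.51% ± 0 in LMPP, 23.1% ± 7.67 and 7.23% ± 3.15 in ALP, and 16.9% ± 4.32 and 2.90% ± 0.0594 in BLP (SD, n = 2 each), and Ctsg passed no share test between genotypes. From ALP to BLP in control mice 12 genes passed, with Ly6d (adjusted p = 1.46e-08), Cd79a (adjusted p = 1.89e-05), Vpreb2 (adjusted p = 0.000356), Dlg2 (adjusted p = 0.000695) and Ebf1 (adjusted p = 0.00377) foremost, and in null mice Ly6d was the 1 gene that passed (adjusted p = 2.88e-08). A gene past the threshold in control mice and not in null mice is not shown to differ between them, and the interactions gave 0 genes by this test in both steps.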
